A study of Arabidopsis thaliana with 12 samples.

How the data were processed

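The series holds 12 arrays of total RNA from Arabidopsis thaliana, ecotype Col-0, in 4 groups of 3 arrays. L-AOPP (2-aminooxy-3-phenylpropionic acid) is a small molecule that blocks phenylalanine ammonia-lyase and, as the series text states, auxin biosynthesis. IAA (indole-3-acetic acid) is the main natural auxin. Per the labels' protocols, plants grew from seed on agar plates with MS medium at 21 °C under 24 h light. The plates held 50 µM L-AOPP, 50 µM L-AOPP with 10 nM IAA, or 0.1% of the solvent DMSO as mock treatment. No DMSO content is given for the plates with L-AOPP, so whether the solvent was matched is not known. The shoot apical meristem part (SAM) was cut out under a microscope with a fine knife and frozen. Whole mock plants were frozen without dissection. The sample labels give the plant age as 4 days and the series text as 7 days, and which of them holds is not settled here.

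The values are linear signal intensity per probe set, deposited in 1 table with a column per array. Per the submitters' processing notes the tool was MAS5, with no version given. The deposited intensity values had already been brought to a common scale per array: after the lowest 2% and highest 2% of each array were left out, the mean lay between 499.7 and 499.8 on every array. The array medians ran from 166 to 194. The table has no detection calls, so absence of a transcript cannot be stated from it. The 3 arrays in each group limit the precision of each value. Nothing in the labels says that the replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

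From the deposited values, log2 was taken with no further scaling. The 64 Affymetrix control probe sets were set aside, and of the other 22746 probe sets the 30% with the lowest mean log2 over all arrays (6824, called dim here) were left out, so that 15922 were tested. Linear models were fitted with limma 3.58.1 (lmFit, then eBayes with an intensity trend) in R 4.3.3. There was 1 coefficient per group over all 12 arrays, which leaves 8 residual degrees of freedom. All tests were two-sided. The Benjamini-Hochberg adjustment was over the 15922 probe sets unless another is stated, and a probe set was called at an adjusted p below 0.05. The comparisons were L-AOPP against mock, L-AOPP with IAA against L-AOPP, and L-AOPP with IAA against mock, all in the SAM, and mock SAM against mock whole plants. A probe set counted as moved back when L-AOPP changed it against mock and L-AOPP with IAA changed it against L-AOPP in the other direction. Fold changes and their SE come from these models, and signals are means with the SD over 3 arrays. Adjusted p-values in the text are limma's unless another test is named.

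Gene names came from the platform annotation supplied with the data, which can be old. It gave exactly 1 gene for 13513 of the 22746 probe sets and several genes for 503, and 8730 probe sets were not listed in it and stay unnamed here. Of the probe sets tested, 8775 had 1 gene. Locus codes were matched through the gene table of assembly TAIR10.1, used for names only, and 13484 of the 13513 matched. No probe set with several genes is named.

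The design, the alternatives, the gene lists and the rule for naming genes were fixed before the data were examined. There were 27 lists with 568 different genes, of which 71 were named on the array and 56 tested. In 22 lists at least 1 member was tested. The other 5, on SAUR genes, auxin transport and perception, shikimate and aromatic amino acid synthesis, nitrogen assimilation, and gibberellin and brassinosteroid synthesis, had 0 tested members and give no result. Members were counted as higher or lower after adjustment over all probe sets and adjusted over the list alone. The latter is not adjusted for the number of lists, and with 1 tested member it leaves the p unadjusted. HCT, RTE1, EXPA18, ICL, PDF1.2, SAG101, UGT74B1 and IRX10 were each the only tested member of a list. The 9 lists with at least 3 tested members were tested with camera (limma, preset correlation 0.01, adjusted over the lists of a comparison), again with an estimated correlation, and with fry. Named genes are, per comparison, the 8 with the largest rise and the 8 with the largest fall among called probe sets with 1 gene whose groups do not overlap, which happens by chance for 10% of probe sets with 3 arrays against 3. From each list they are up to 4 called members with the largest difference, or the 2 with the smallest p where none was called. For the return toward mock they are the 10 genes with the largest L-AOPP difference. TAA1, TAR2, PAL1, PAL2 and PAL4, which the rule also named, are not analysed here. Genes named outside the rule are said to have been chosen after their values were seen.

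The alternatives were quantile normalization, median centring, a floor at the 20th percentile (19.4), a pseudocount at the 25th percentile (28.4), no filter, a filter on the lowest 50%, only the 2 groups compared, only the 9 SAM arrays, no intensity trend, array weights, the replicate number as a block, and leaving out each array in turn. The log2 ratio of the 3' to the 5' GAPDH control signal, as a covariate, was added after seeing that this ratio differed between groups. The comparisons share arrays, so overlaps between them were set beside 100 simulations without the effect in question.

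The models were tested on simulated data with 200 of the 15922 probe sets changed by a log2 size of 0.5, 1 or 2 and with the moderated SD that limma gave each probe set. For L-AOPP against mock, 28.4%, 91% and 98.5% of these were recovered, with 11 false calls. For L-AOPP with IAA against L-AOPP the shares were 29.9%, 83.6% and 93.9%, with 9 false calls. For L-AOPP with IAA against mock they were 43.3%, 76.1% and 97%, with 8 false calls, and for SAM against whole plants 43.3%, 82.1% and 97%, with 14 false calls. In each comparison a simulated list of 7 shifted by a log2 size of 1 was recovered, and 0 of the unshifted lists among the 9 were called. The simulated noise was independent between probe sets, while the estimated correlation within a real list reached 0.841. The simulations therefore give no error rate of camera for the real lists. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.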

Results

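Transcript levels were measured in the dissected shoot apical meristem part (SAM) of plants grown with L-AOPP, with L-AOPP and IAA, or with DMSO (mock). Whole mock plants were measured as well, and each group had 3 arrays. The series text places the experiment in the study of L-AOPP as an inhibitor of auxin biosynthesis. Spearman correlations between arrays of 1 group ran from 0.974 to 0.982, those between arrays of different SAM groups from 0.968 to 0.98, and those between SAM and whole plants from 0.89 to 0.904. RNA quality signs differed between arrays. The 25S rRNA control had a signal of 164 on mock SAM replicate 3 and of 5170 to 10330 on the other 11 arrays. The log2 ratio of the 3' to the 5' GAPDH control was 0.97 ± 0.04 (SD, n = 3) in whole plants, 1.78 ± 0.36 in mock SAM, 1.5 ± 0.12 with L-AOPP and 1.29 ± 0.06 with L-AOPP and IAA. In exact two-sided permutation tests of this ratio, p was 0.4 for L-AOPP against mock and 0.1, the smallest that 3 arrays against 3 allow, for each of the other 3 comparisons. For the actin control p was 0.5 for L-AOPP against mock and 0.1 for the other 3 (exact permutation). The ratio of the ubiquitin control differed by -0.23 for L-AOPP against mock, -0.3 for L-AOPP with IAA against mock and 0.34 for SAM against whole plants (exact permutation p 0.1 each). For L-AOPP with IAA against L-AOPP it differed by -0.07 (exact permutation p 0.5).

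**Figure D1:**
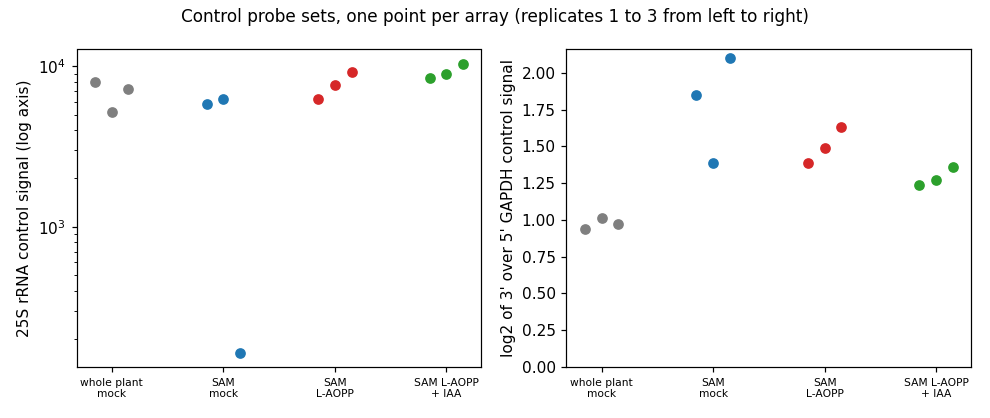
Signal of the 25S rRNA control on a log axis and log2 ratio of the 3' to the 5' GAPDH control signal, 1 point per array in the 4 groups. Mock SAM replicate 3 lies at 164 for the rRNA control, and the GAPDH ratio of the mock SAM arrays runs from 1.39 to 2.1.

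The comparison of mock SAM with mock whole plants shows which transcripts the dissected part held. All 5 measured genes of the shoot meristem and organ boundary list were higher in the SAM. PHV was 4.6-fold higher (log2 2.2 ± 0.11 SE, n = 3), UFO 4.47-fold (2.16 ± 0.22) and LAS 3.44-fold (1.78 ± 0.25). CLV3, the stem cell peptide of the shoot meristem, rose from 24.6 ± 22.7 (SD) to 143 ± 42.4 (3.24 ± 0.70 SE). With 1 of its arrays below the floor of 19.4, its log2 difference was 2.32 with the floor, and its call was lost with the GAPDH ratio as a covariate (adjusted p 0.281). All 3 measured cell cycle genes were higher, the Aurora kinases AUR2 (1.83 ± 0.08) and AUR1 (1.23 ± 0.09) and the replication gene MCM7 (1.4 ± 0.12). All 4 measured photosynthesis genes were lower: the Calvin cycle genes PRK (-2.14 ± 0.08) and SBPASE (-2.06 ± 0.08), the Rubisco activase gene RCA (-1.08 ± 0.08) and the antenna gene LHCB4.1 (-0.96 ± 0.07). With camera these 3 lists had adjusted p-values of 0.0272, 0.0272 and 0.000368, and each had an adjusted p of 0.132 with an estimated correlation. No camera call in any comparison held with an estimated correlation. With fry, which takes each list by itself, all but the auxin inactivation (adjusted p 0.175) and flavonoid (0.0741) lists passed, at adjusted p-values up to 0.00354.

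Of the auxin genes, 3 of 4 GH3 genes, whose enzymes conjugate auxin, were higher in the SAM: GH3.3 by 3.19 ± 0.18, GH3.5 by 2.13 ± 0.17 and GH3.17 by 1.88 ± 0.12 (camera adjusted p 0.0539). Among 3 Aux/IAA genes IAA30 was higher (2.11 ± 0.19). The median of that list was -0.13, while camera gave the direction up (adjusted p 0.965). The auxin synthesis gene YUC4 was higher (3.66 ± 0.49; 3.02 with the floor) and YUC2 lower (-1.12 ± 0.36), the auxin-inducible HAT2 was higher (0.66 ± 0.14) and XTH19 lower (-3.41 ± 0.20), and DAO2, of 3 auxin inactivation genes, was lower (-0.46 ± 0.14; camera adjusted p 0.443). The YUC2 call was lost without mock SAM replicate 3 (adjusted p 0.0638) and without whole plant replicate 2 (0.0591). Of 7 flavonoid and anthocyanin genes 5 were higher, among them DFR (1.88 ± 0.32) and UGT75C1 (1.56 ± 0.32), and 1 was lower (camera adjusted p 0.443). The cytokinin response gene ARR15 was higher (2.45 ± 0.14) and ARR16 lower (-1.08 ± 0.23). The glucosinolate genes BCAT4 (2.42 ± 0.24), UGT74C1 (1.36 ± 0.13) and UGT74B1 (1.4 ± 0.12), the defensin gene PDF1.2 (2.21 ± 0.22) and the ethylene response gene RTE1 (0.67 ± 0.12) were higher.

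Lower in the SAM were the detoxification genes GSTU25 (-5.37 ± 0.31, 41.4-fold) and UGT73B5 (-1.57 ± 0.30), the root marker EXPA18 (-3.46 ± 0.40), the lignin gene HCT (-0.76 ± 0.08) and ZAT10 (-2.42 ± 0.50; -2.28 with the floor), the only called gene of 3 on the wound list (camera adjusted p 0.262). Of 7 cell wall expansion genes 5 were lower, with XTH18 at -4.57 ± 0.73 (-4.1 with the floor) and XTH33 at -1.79 ± 0.30, and 2 were higher, among them EXPA15 (1.11 ± 0.13; camera adjusted p 0.138). Over each list alone the same number of members passed as over all probe sets (adjusted over the list alone). SAG101 (0.30 ± 0.29, adjusted p 0.378) and IRX10 (0.00 ± 0.17, adjusted p 0.996) did not pass. ICL, for isocitrate lyase of the glyoxylate cycle, was lower (-1.94 ± 0.77, adjusted p 0.0355). That call was lost without any 1 of the 6 arrays, with adjusted p-values of 0.0977, 0.0609 and 0.0594 without mock SAM replicates 1 to 3 and of 0.0749, 0.0786 and 0.0702 without whole plant replicates 1 to 3.

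Outside the lists, AT4G22490 rose from a signal of 208 ± 32.6 (SD, n = 3) in whole plants to 6998 ± 1440 in the SAM (5.06 ± 0.35, 33.4-fold). For 7 other genes named for their rise, at least 2 whole plant arrays lay below the floor of 19.4, so their sizes with the floor are lower bounds without an order: 4.67 for AT5G59330, 4.52 for AT3G06220, 3.55 for AT3G59270, 3.36 for AT1G76960, 2.99 for AT4G31615, 2.85 for AT1G26680 and 2.58 for AT4G22510. AT1G52070 fell from 2714 ± 113 to 9.23 ± 5.06, below the floor, which bounds its log2 difference at -7.13 or lower. Such bounds were -7.02 for AT5G64100, -6.82 for AT3G16670, -6.71 for AT1G52060, -6.13 for AT1G52050 and -5.5 for AT2G48130. AT2G37130 and AT5G62340 had only 1 SAM array each below the floor. With the floor their log2 differences were -7.38 and -6.35. In all, 6787 probe sets were higher and 3973 lower of 15922, with 2363 and 1881 of them at least 2-fold. The median log2 difference over all probe sets was 0.205, 0.159 after quantile normalization and 0.071 after median centring, and the changes named here keep their sign relative to it. The GAPDH ratio differed most in this comparison, and with it as a covariate, chosen after seeing the data, 3965 were higher and 2291 lower. With it the calls of 14 named genes were lost: CLV3, YUC2 (-0.13, adjusted p 0.901), DAO2 (-0.08, 0.825), HAT2 (0.30, 0.402), UGT73B5 (-0.81, 0.299), ICL (0.275), UGT79B1 (0.181), DFR (0.138), RTE1 (0.138), 5MAT (0.125), ARR16 (0.083), UGT75C1 (0.0653), AT2G48130 (0.0607) and AT4G22510 (0.0532).

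**Figure D2:**
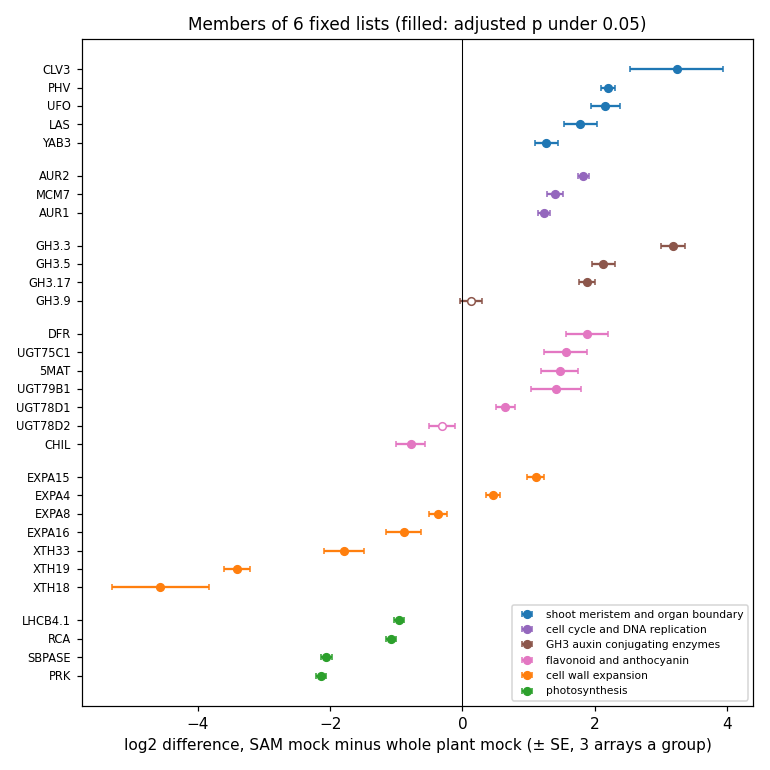
Log2 difference between mock SAM and mock whole plants for the measured members of 6 gene lists, with the SE from limma (3 arrays per group). Filled points have an adjusted p below 0.05, and the 5 meristem genes lie above 0 and the 4 photosynthesis genes below 0.

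L-AOPP against mock asks what the inhibitor did in the SAM. ATC, a relative of the floral repressor TFL1, rose from a signal of 9.37 ± 10.7 (SD, n = 3), below the floor of 19.4, to 115 ± 9.12 (log2 4.32 ± 0.73 SE, adjusted p 0.00723). With the floor its log2 difference was 2.51, a lower bound, and with the pseudocount 1.96. In whole plants ATC had a signal of 493 ± 23.2 (SD), looked up after the results were seen. Mock SAM, below the floor, was lower than that (log2 -6.42 ± 0.73 SE, adjusted p 1.21e-06). AT5G12110 rose 2.29-fold (1.19 ± 0.18) and AT3G43670 2.2-fold (1.14 ± 0.15). AT1G47400, a gene induced by iron deficiency, fell 4.52-fold (-2.18 ± 0.26, adjusted p 0.000637), from 840 ± 228 to 183 ± 31.3, and AT5G05250 fell 3.62-fold (-1.85 ± 0.30). AT1G59740 (-1.68 ± 0.13, adjusted p 1.32e-05), the subtilase gene SBT4.12 (-1.64 ± 0.20) and the thionin gene THI2.2 (-1.21 ± 0.18) also fell. These 8 genes were called without any 1 array.

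AT3G04000 (2.07 ± 0.44), AT4G24110 (1.93 ± 0.48), AT5G37990 (1.43 ± 0.25) and AT3G50570 (1.37 ± 0.30) rose as well, and AT3G01350 (-1.40 ± 0.26), AT4G15700 (-1.35 ± 0.27) and ARLA1B (-1.43 ± 0.36; -1.4 with the floor) fell. AT3G04000 had a mock signal of 11.8, below the floor, with which its log2 difference was 1.17 and its call was lost (adjusted p 0.0543). Each of these 7 lost its call without at least 1 array. For AT5G37990 this was L-AOPP replicate 2 (adjusted p 0.0602), and for AT3G01350 L-AOPP replicate 2 (0.0565) and mock replicate 1 (0.0642). AT4G15700 lost it without L-AOPP replicates 1 and 2 (0.0795, 0.0898) and mock replicate 1 (0.0933). For AT3G04000 the arrays were L-AOPP replicates 1 to 3 (0.0744, 0.118, 0.0517) and mock replicate 3 (0.0729). AT4G24110 (0.123 to 0.175), AT3G50570 (0.0703 to 0.123) and ARLA1B (0.0743 to 0.196) lost it without any 1 array but mock replicate 2. ICL fell from 47.6 ± 10.3 to 3.70 ± 2.17 (-3.81 ± 0.77, adjusted p 0.0196), below the floor. Its log2 difference was -1.27 with the floor and -1.24 with the pseudocount. Its call ended with the floor (0.3), the pseudocount (0.143), no intensity trend (0.0688) and the GAPDH ratio as a covariate (0.142), and without L-AOPP replicates 1 and 3 (0.0744, 0.0646) and without mock replicates 1 and 3 (0.0584, 0.0686).

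Of the 2 measured genes of the other auxin-inducible list, HAT2, for a homeodomain-leucine zipper protein, fell from 639 ± 99.7 to 379 ± 50.5 (log2 -0.75 ± 0.14, adjusted p 0.0115). The call was lost without L-AOPP replicate 1 (0.0516) or 3 (0.0527) and mock replicate 1 (0.0617) or 3 (0.0513). None of the 3 Aux/IAA genes passed (camera adjusted p 0.577), with IAA29 at -0.33 ± 0.34 and IAA30 at -0.13 ± 0.19. Of 4 GH3 genes 0 passed over all probe sets and 1 was lower when adjusted over the list alone, GH3.17 (-0.41 ± 0.12; camera adjusted p 0.0691). For auxin synthesis the counts were 0 of 2 and, adjusted over the list alone, 1 higher, YUC2 (0.94 ± 0.36). Among 3 auxin inactivation genes they were 0 and, adjusted over the list alone, 2 higher, UGT74D1 (0.48 ± 0.16) and DAO2 (0.40 ± 0.14; camera adjusted p 0.0603).

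The 5 measured meristem genes had a median of -0.54 and a camera adjusted p of 0.0381 (down), and an adjusted p of 0.149 with an estimated correlation. No member passed over all probe sets and UFO did when adjusted over the list alone (-0.80 ± 0.22). The 7 cell wall expansion genes had a median of -0.41 and a camera adjusted p of 0.0309 (down), and an adjusted p of 0.149 with an estimated correlation. None passed over all probe sets, and 3 were lower when adjusted over the list alone, among them EXPA8 (-0.53 ± 0.14) and EXPA4 (-0.32 ± 0.11). The camera calls of both lists were lost without L-AOPP replicate 1 (adjusted p 0.0511 for each), L-AOPP replicate 2 (0.0753 for each) and mock replicate 3 (0.0868 and 0.0762). With the GAPDH ratio as a covariate, the adjusted p was 0.0866 for each. The meristem call was also lost with the filter on the lowest 50% (0.378) and with array weights (0.0598). With fry 6 lists passed: cell cycle (adjusted p 0.0074), meristem and cell wall expansion (0.0293 each), auxin inactivation and wound (0.031 each) and GH3 (0.0359).

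Of 3 genes on the wound list the calmodulin-like CML38 rose (1.83 ± 0.46, adjusted p 0.046; camera adjusted p 0.0973). The call was lost without any 1 array (0.104, 0.15 and 0.137 without L-AOPP replicates 1 to 3, 0.173, 0.0813 and 0.0693 without mock replicates 1 to 3). Adjusted over the list alone, ARR16 (0.82 ± 0.23) was higher and ARR15 (-0.30 ± 0.14) lower of 2 cytokinin genes. By the same count AUR1 (0.21 ± 0.09) and AUR2 (0.22 ± 0.08) were higher of 3 cell cycle genes (camera adjusted p 0.0973). UGT73B5 (0.90 ± 0.30, of 2 detoxification genes) and HCT (0.27 ± 0.08), the only tested gene of its list, were higher too. Over all probe sets 0 of these passed. None passed by either count among 4 photosynthesis genes (camera adjusted p 0.723; SBPASE 0.09 ± 0.08), 7 flavonoid genes (0.339; 5MAT 0.36 ± 0.28) and 2 aliphatic glucosinolate genes (BCAT4 -0.22 ± 0.24). The same held for EXPA18 (-0.55 ± 0.40), PDF1.2 (-0.41 ± 0.22), SAG101 (0.29 ± 0.29), UGT74B1 (-0.04 ± 0.12), RTE1 (-0.22 ± 0.12) and IRX10 (-0.07 ± 0.17).

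Over all probe sets 194 were higher and 214 lower with L-AOPP, of which 34 and 27 at least 2-fold. Without L-AOPP replicates 1, 2 and 3 the counts were 40 and 54, 35 and 54, and 67 and 87. Without mock replicates 1, 2 and 3 they were 52 and 48, 295 and 291, and 71 and 92. With the GAPDH ratio as a covariate, which differed by -0.28 between these groups, 26 were higher and 21 lower, and without the intensity trend 52 and 70. With the covariate 14 of the 23 called named genes lost the call: AT4G24110 (adjusted p 0.279), ARLA1B (0.274), AT3G50570 (0.228), CML38 (0.162), MSRB5 (0.156), AT4G15700 (0.15), ICL (0.142), HAT2 (0.126), UGT87A2 (0.117), AT3G04000 (0.113), AT5G41400 (0.112), AT3G01350 (0.0912), AT5G37990 (0.0558) and AT5G05250 (0.0511). A lost call can come from lower precision as well as from a smaller difference. AT5G05250 had a log2 difference of -1.85 with and without the covariate, and sizes with it are not given here for the rest. With median centring 194 were higher and 171 lower.

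**Figure D3:**
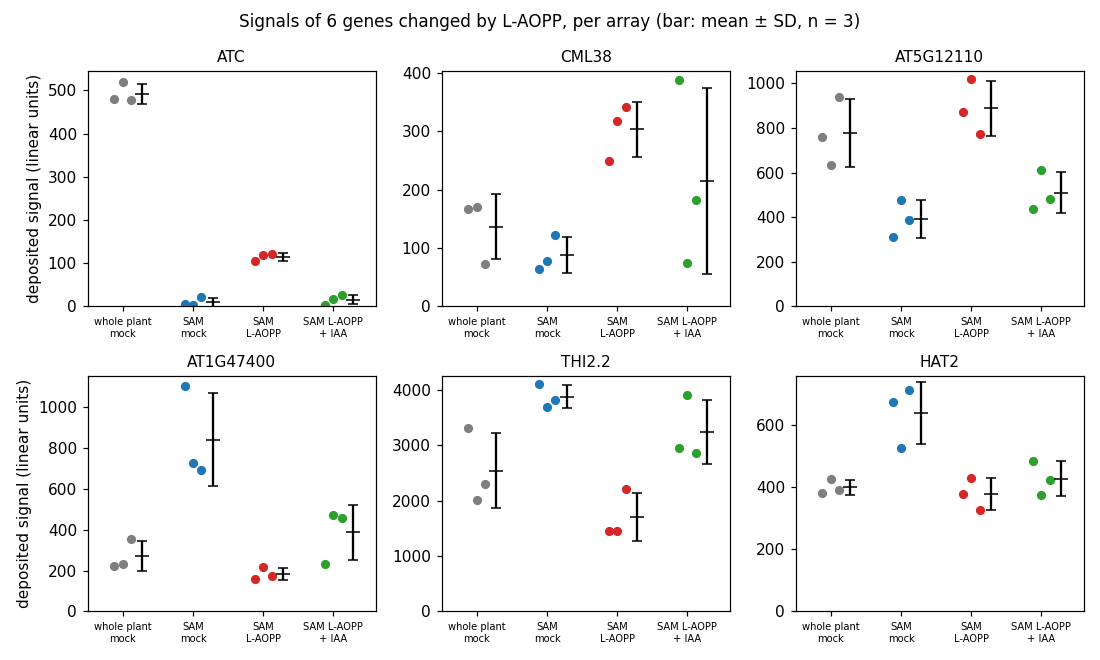
Signal of ATC, CML38, AT5G12110, AT1G47400, THI2.2 and HAT2 on each of the 3 arrays of the 4 groups, with bars for the mean and SD. ATC averages 9.37 in mock SAM and 115 with L-AOPP, and AT1G47400 averages 840 and 183.

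L-AOPP with IAA against L-AOPP asks what added auxin changed in inhibitor-treated plants. XTH16, of a family of cell wall enzymes, rose from 1645 ± 81.2 to 2885 ± 273 (SD, n = 3; log2 0.81 ± 0.09 SE, adjusted p 0.00146) and AT5G26280 rose 1.9-fold (0.93 ± 0.12). AT2G25510 fell 1.93-fold (-0.95 ± 0.11, adjusted p 0.00139). These 3 genes were called without any 1 array. THI2.2 rose 1.92-fold (0.94 ± 0.18), and ICL rose from 3.70 ± 2.17 to 137 ± 107 (4.62 ± 0.77, adjusted p 0.0115; 2.24 with the floor). This call was lost with the floor (0.108), with only the 2 groups compared (0.096), without the intensity trend (0.0678), without L-AOPP with IAA replicate 3 (0.0674) and without L-AOPP replicate 1 (0.0596). ATC fell from 115 ± 9.12 to 15.5 ± 11.1 (-3.27 ± 0.73, adjusted p 0.0483; -2.42 with the floor), a call lost without any 1 array (0.0586 to 0.188). AT5G59330 fell from 829 ± 129 to 139 ± 165 (-3.28 ± 0.62) and AT1G28710 from 1063 ± 149 to 277 ± 234 (-2.24 ± 0.39).

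AT2G43600 (-2.87 ± 0.44; -2.23 with the floor), AT2G19970 (-2.72 ± 0.51), AT2G23540 (-2.72 ± 0.47), AT5G44380 (-2.47 ± 0.46) and AT1G01640 (-2.38 ± 0.47) fell, and AT3G59340 (1.02 ± 0.22), the cysteine proteinase gene CP1 (1.01 ± 0.22), AT4G18650 (1.00 ± 0.22) and AT1G54120 (0.90 ± 0.19) rose. With IAA the signals of AT2G19970, AT5G44380, AT1G01640 and AT2G23540 lay below the floor, with which their log2 differences were -1.76, -1.69, -1.25 and -0.73 and the calls of AT1G01640 (adjusted p 0.0559) and AT2G23540 (0.215) were lost. Each of these 9, and THI2.2, AT5G59330 and AT1G28710, lost its call without L-AOPP replicate 1, with adjusted p-values of 0.0519 for AT2G43600 to 0.171 for CP1, and all but AT2G43600 lost it without at least 1 further array. Of the list genes measured, ICL was called and 0 others. Adjusted over the list alone, UFO (0.79 ± 0.22), EXPA18 (1.00 ± 0.40) and 2 of 7 cell wall expansion genes, among them EXPA8 (0.53 ± 0.14), were higher. By that count ARR16 (-0.64 ± 0.23), PDF1.2 (-0.63 ± 0.22), BCAT4 (-0.77 ± 0.24) and EXPA4 (-0.37 ± 0.11) were lower. EXPA18 and PDF1.2 were the only tested genes of their lists, so their p stayed unadjusted. The 9 lists tested with camera had adjusted p-values of 0.0948 (meristem and cell wall expansion, both up) to 0.96, and none passed, nor did any with fry (0.0852 to 0.962). No Aux/IAA gene (IAA29 0.30 ± 0.34), GH3 gene (GH3.17 0.32 ± 0.12), auxin synthesis gene (YUC2 -0.23 ± 0.36), auxin inactivation gene (DAO2 0.32 ± 0.14) or other auxin-inducible gene (XTH19 0.46 ± 0.20) passed by either count.

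Over all probe sets 44 were higher and 93 lower, of which 6 and 50 at least 2-fold. Without L-AOPP with IAA replicates 1, 2 and 3 the counts were 60 and 153, 28 and 53, and 9 and 22. Without L-AOPP replicates 1, 2 and 3 they were 10 and 18, 11 and 23, and 14 and 43. The GAPDH ratio differed by -0.21 between these groups and gave 22 higher and 48 lower as a covariate, with which 12 named genes lost the call: ATC and AT3G59340 (adjusted p 0.12 each), CP1 (0.118), AT1G06100 (0.112), AT1G54120 (0.101), MSRB5 (0.0887), AT4G18650 (0.088), AT2G19970 (0.0713), AT1G01640 (0.07), AT5G59330 (0.0575), THI2.2 (0.055) and AT5G44380 (0.0519). Without the intensity trend the counts were 5 and 18, with only the 2 groups compared 27 and 39, with only the 9 SAM arrays 58 were lower, with the filter on the lowest 50% 51 were lower, and with array weights 103 were higher.

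Of the 408 probe sets that L-AOPP changed, 23 moved back with IAA. Of these, 15 were raised by L-AOPP and lower with IAA, and 8 lowered and higher with IAA. The 10 named genes of this set were ATC, ICL, AT3G50570 (1.37 with L-AOPP, then -1.63 with IAA), THI2.2 (-1.21, then 0.94), AT5G12110 (1.19, then -0.81), AT1G06100 (1.02, then -0.75), the glycosyltransferase gene UGT87A2 (0.92, then -0.83), the methionine sulfoxide reductase gene MSRB5 (0.71, then -0.90), AT5G41400 (-0.66, then 0.63) and AT2G25510 (0.66, then -0.95). In the comparison of L-AOPP with IAA against mock their log2 differences ran from -0.29 to 1.04 and none of the 10 passed. Of those raised by L-AOPP, ATC (-6.42), UGT87A2 (-2.07), AT3G50570 (-1.56), AT5G12110 (-0.99) and MSRB5 (-0.88) were lower in mock SAM than in whole plants. AT1G06100 (0.61) and AT2G25510 (0.56) were higher there. These SAM differences were looked up after the results were seen, and other tissue in the tips was not tested for this set. AT2G25510 kept both calls without any 1 array, and the other 9 lost the IAA call without L-AOPP replicate 1, with adjusted p-values of 0.0596 for ICL to 0.142 for ATC. AT3G45160, named after its values were seen, was the only probe set lowered by L-AOPP (-0.73) and further by IAA (-0.72).

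The 2 comparisons share the L-AOPP arrays. Independent lists of these sizes would share 1.13 and 0.591 probe sets in these directions. In 100 simulations of unchanged groups a mean of 0.05 moved back (highest 1), as did 0.06 (highest 1) in those with the L-AOPP differences and no IAA effect. These simulations called a mean of only 0.25 and 0.21 probe sets for IAA, against 137 in the data. With so few calls their numbers moved back had to lie near 0, so they give no measure for the 23. The covariance of the log2 differences was -0.0360 and that of the unchanged simulations -0.0209. Their correlation was -0.416, weaker than the -0.4997 of the unchanged simulations and within the range of those with the L-AOPP differences and no IAA effect (-0.417, -0.439 to -0.388). Of the 408 probe sets, 353 (86.5%) had an IAA difference opposite in sign to the L-AOPP difference. The share was 57.8% (50.8% to 65.7%) in simulations with the L-AOPP differences and no IAA effect, and 94.4% of the few called in unchanged ones. The former took the estimates of the called probe sets as true differences. Selection makes such estimates too large on average, which lowers the 57.8%. Whether 86.5% exceeds the share without an IAA effect is therefore not settled. Part of the excess over independent lists may come from the shared arrays. Without L-AOPP with IAA replicates 1 and 3 the count moved back was 38 and 4, without L-AOPP replicates 1, 2 and 3 it was 5, 5 and 8, and without mock replicate 1 it was 10. It was 14 with no filter or with the filter on the lowest 50%, 5 without the intensity trend, 46 with array weights and 3 with the GAPDH ratio as a covariate.

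**Figure D4:**
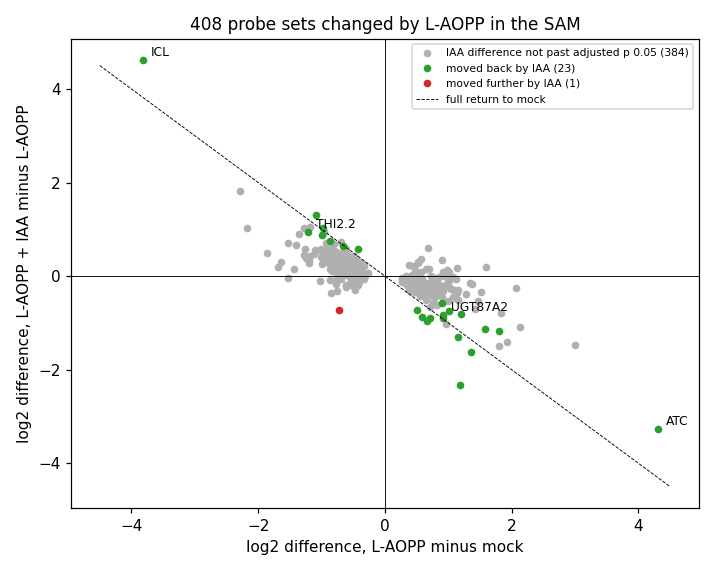
Log2 difference of L-AOPP against mock (x axis) and of L-AOPP with IAA against L-AOPP (y axis) for the 408 probe sets that L-AOPP changed. The 23 green points moved back, the 1 red point moved further the same way, the 384 grey points did not pass on the y axis, and the dashed line marks a full return to the mock level.

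L-AOPP with IAA against mock gives what remained or was added in plants that had both compounds. Of the list genes, DAO2, for an auxin-oxidizing enzyme, rose (log2 0.71 ± 0.14 SE, adjusted p 0.0119, n = 3), and EXPA4 (-0.69 ± 0.11, adjusted p 0.00608), PDF1.2 (-1.03 ± 0.22), BCAT4 (-0.98 ± 0.24) and HAT2 (-0.57 ± 0.14) fell. The expansin gene EXPA4 was 1 of 7 cell wall expansion genes called, BCAT4 1 of 2 aliphatic glucosinolate genes and HAT2 1 of 2 other auxin-inducible genes. The 3 auxin inactivation genes had a median of 0.51 and a camera adjusted p of 0.0144 (up), and an adjusted p of 0.189 with an estimated correlation. Adjusted over the list alone, 2 auxin inactivation genes, 1 of the other auxin-inducible genes and HCT (0.22 ± 0.08), the only tested gene of its list, were higher. The camera call was lost without L-AOPP with IAA replicate 2 (adjusted p 0.0678) and with the GAPDH ratio as a covariate (0.207). DAO2 lost its call without L-AOPP with IAA replicate 2 (0.055) and mock replicate 3 (0.053). HAT2, PDF1.2 and BCAT4 lost theirs without mock replicate 3 (0.146, 0.0961, 0.161), L-AOPP with IAA replicates 2 (0.135, 0.09, 0.0927) and 3 (0.0872, 0.0761, 0.134) and, for HAT2, mock replicate 1 (0.11), for PDF1.2, mock replicate 2 (0.0596), and for BCAT4, mock replicates 1 (0.0719) and 2 (0.0507). The other 8 lists tested with camera had adjusted p-values of 0.296 to 0.866. With fry auxin inactivation and the cell cycle passed (adjusted p 0.00676 each). No member of the other lists passed by either count, with medians of -0.03 for 3 Aux/IAA genes, -0.17 for 4 GH3 genes and -0.1 for 5 meristem genes.

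Higher with L-AOPP and IAA than in mock were AT3G43670 (2.5-fold, 1.32 ± 0.15, adjusted p 0.000577), AT1G43910 (1.25 ± 0.22), AT5G41940 (2.11 ± 0.47; 1.82 with the floor), AT3G04000 (1.83 ± 0.44), AT5G16980 (1.41 ± 0.27), the sugar transporter gene SWEET11 (1.31 ± 0.29) and the plastid genome genes ycf3 (1.92 ± 0.40) and petG (1.39 ± 0.33). Lower were AT2G43600 (-3.19 ± 0.44, adjusted p 0.00179; -2.55 with the floor), AT5G59330 (-2.84 ± 0.62), AT1G01640 (-2.64 ± 0.47), AT2G41800 (-2.50 ± 0.54), AT1G28710 (-2.12 ± 0.39), AT5G44380 (-2.05 ± 0.46), AT5G48430 (-2.03 ± 0.40) and AT4G22490, whose signal was 2047 ± 1620 against 6998 ± 1440 (-2.03 ± 0.35). Below the floor lay AT3G04000 in mock and AT1G01640, AT5G44380 and AT2G41800 with L-AOPP and IAA. With the floor their log2 differences were 0.93, -1.5, -1.27 and -0.66, and the calls of AT3G04000 (0.117) and AT2G41800 (0.261) were lost. Of the genes named here AT3G43670, AT1G43910, AT2G43600, AT1G01640, AT1G28710, AT4G22490 and EXPA4 were called without any 1 array. The other 10 of this paragraph lost the call without mock replicate 3, with adjusted p-values of 0.0527 for AT5G16980 to 0.145 for petG, and 9 of them without at least 1 further array.

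Over all probe sets 194 were higher and 290 lower than in mock, of which 25 and 72 at least 2-fold. The GAPDH ratio differed by -0.49 between these groups, and with it as a covariate 4 were higher and 3 lower and none of the 21 called named genes passed. Without L-AOPP with IAA replicate 1 the counts were 125 and 280, without replicate 2 they were 77 and 136, and without replicate 3 they were 118 and 170. Without mock replicate 1 they were 111 and 119 and without mock replicate 3 they were 62 and 107. With only the 2 groups compared they were 51 and 83, without the intensity trend 62 and 113, and with only the 9 SAM arrays 128 were higher.

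Against mock, 123 probe sets changed in the same direction with L-AOPP and with L-AOPP and IAA, 60 higher and 63 lower, while 284 passed with L-AOPP alone and 360 with L-AOPP and IAA alone. Only 1 unnamed probe set, among the 23 moved back, passed in opposite directions. Its log2 difference was 1.18 with L-AOPP and -1.14 with L-AOPP and IAA (adjusted p 0.0078). Independent lists would share 2.36 and 3.9, and unchanged simulations a mean of 0.03. The unchanged simulations called a mean of only 0.21 probe sets for L-AOPP, so their overlap had to lie near 0. Simulations with the L-AOPP differences and no IAA effect shared a mean of 283 (259 to 308), a number raised by their use of selected estimates as true differences. The covariance of the log2 differences was 0.0554, with 0.0210 in the unchanged simulations and 0.0391 (0.0363 to 0.0409) with no IAA effect. Their correlation was 0.576, with 0.501 in the unchanged simulations and 0.652 (0.63 to 0.675) with no IAA effect. The mock arrays are shared by both comparisons and may account for part of the excess over independent lists.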

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

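The tests of other splits were planned, and the tests of the 3 patterns and of the GAPDH covariate were chosen only after the results were seen. Of the 64 control probe sets, 7 were higher and 5 lower in mock SAM than in whole plants, in data that the comparisons leave out. The controls were fitted without the intensity trend and adjusted over the 64. For the 6824 dim probe sets left out of the tests, calls come from the fit with no filter, adjusted over all 22746. Of these dim probe sets, 7 were higher and 7 lower with L-AOPP than in mock. In mock SAM, 155 were higher and 1057 lower than in whole plants. With L-AOPP and IAA, 3 of these dim probe sets were higher and 1 lower than with L-AOPP, the only named one among the 3 being AT2G01700 (log2 4.25, adjusted p 0.0195), chosen after its values were seen. Against mock, 11 of them were higher and 5 lower with L-AOPP and IAA.

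With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 408 changed probe sets for L-AOPP against mock (highest of the other splits 0), 137 for L-AOPP with IAA against L-AOPP (0), 484 for L-AOPP with IAA against mock (3), 10760 for SAM against whole plants (0) and 23 moved back (0), so 1 split, the real one, gave as many in each. For lists past the camera threshold, the real values were 2, 0, 1 and 3, the highest of the other splits 2, 2, 3 and 1, and the number of splits with as many 2, 10, 7 and 1, in the order of those 4 comparisons.

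The 92 probe sets with a log2 SAM difference above 3 had a median of -0.25 with L-AOPP, and 72.8% of them lay below 0, though the 95% interval from 1 value per array was -0.51 to 0.01. Mock arrays shared by both differences are argued against as the whole cause, since with no shared mock array the medians were at most -0.18 and the 3 intervals lay below 0. Green tissue mixed into the tips at a share of 13.5%, the lowest estimated from SAM-high probe sets, predicted a median of 0.36 for the 4 photosynthesis genes. Their median was -0.05 (largest SE 0.08), which argues against a share of that size. The uncertainty of the share was not carried into the prediction, so a smaller one is not excluded. In addition, 52 of 68 plastid genome probe sets lay above 0, with a median of 0.23. Other tissue like the whole plant, at a share of 13.5%, predicted a median of at least 1.5 for probe sets with a log2 SAM difference below -3. With no shared mock array their medians were at most 0.26, which argues against a share of that size. Yet these probe sets tended to rise, with intervals from 1 value per array of 0.12 to 0.52, 0.01 to 0.49 and -0.19 to 0.57. The share estimated from them was 0.749% to 0.902%. With mock arrays shared, the median with L-AOPP fell stepwise from 0.68 for the 64 probe sets with a SAM difference of -5 or lower to -0.25 above 3. RNA quality may account for the pattern and stays open, with a median of -0.19 and an interval of -0.50 to 0.13 under the GAPDH covariate. An untested effect of L-AOPP on the makeup of the shoot tip and a neighbouring tissue with a profile not measured here also stay open. So does a smaller share of other tissue, at least for part of the pattern.

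The 50 probe sets at least 2-fold lower with L-AOPP and IAA than with L-AOPP had a median of -1.68. Against mock, their medians were 0.28 with L-AOPP and -1.41 with L-AOPP and IAA, and 35 of the 50 were called lower with both compounds. No group had IAA without L-AOPP. The median SD of the 50 on the log2 scale was 0.72 among the L-AOPP with IAA arrays and 0.22 among those with L-AOPP. Less or more meristem tissue in the tips is argued against as the whole cause, since 10 of them were 2-fold higher and 28 were 2-fold lower in SAM than in whole plants. Of all 15922 probe sets, 2363 were called at least 2-fold higher and 1881 at least 2-fold lower in SAM. The 28 of 50 are a far larger share than that, so a difference in tissue as part of the cause stays open. With the floor 48 stayed called and 2-fold lower, which argues against noise of values below 19.4 as the whole cause for these. The floor also narrows the spread of low values, which makes calls easier, and the set was chosen on these same arrays. Noise of dim signals above the floor is therefore not excluded. From 1 value per array, the median was -1.62 with the GAPDH covariate (95% interval -2.31 to -0.93) and -1.61 without it, and 22 stayed called with it. The set was chosen for its fall on these same arrays, which favours an interval below 0. It is therefore no independent test of RNA quality, and shows only that this ratio did not take up the fall. In 40 of the 50, replicate 1 was the highest of the L-AOPP with IAA arrays. A response to IAA that differed between these arrays is a candidate explanation, and the design gives no test of it.

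PYE, a transcription factor gene of the iron deficiency response (log2 -1.0, adjusted p 0.0377, chosen after its values were seen), AT1G47400 and AT5G05250 were lower with L-AOPP. A lower iron deficiency response could be the reason, but the other 5 measured genes of a 27-gene list had a median of 0.28, all above 0 and none called, which leaves it open. Fewer SAM-high transcripts are argued against, since 2009 probe sets with a log2 SAM difference of 1 to 2, as AT1G47400 (1.64) and AT5G05250 (1.15) have, had a median of -0.06, and those from -1 to 1, as PYE (0.32) has, of -0.01. From 1 value per array, the median for the 3 genes was -1.87 with the GAPDH covariate (95% interval -2.91 to -0.82) and -1.87 without it. Only AT1G47400 stayed called with it (adjusted p 0.0122). The genes were chosen for their fall on these same arrays, which favours an interval below 0. It is therefore no independent test of RNA quality, and shows only that this ratio did not take up the fall.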

How the results depend on the processing

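The GAPDH covariate is the only setting here whose tests were chosen after the results were seen. No called gene named or list changed sign. The surplus of lower probe sets did: L-AOPP against mock had more higher than lower with median centring (194 and 171), the covariate, and without mock replicate 1 or 2, and L-AOPP with IAA against mock with the covariate. Of 123 calls of named genes, with a gene counted once per comparison, 74 held without any 1 array and 54 in every setting. SAM against whole plants gave 54 of these 74 and 42 of these 54. In every setting 9 of 23 calls held for L-AOPP against mock and 3 of 23 for L-AOPP with IAA against L-AOPP. For L-AOPP with IAA against mock 0 of 21 did. For L-AOPP against mock, 194 higher and 214 lower became 52 and 70 without the intensity trend and 26 and 21 with the covariate, and ran from 35 to 295 and from 48 to 291 when 1 array was left out. For L-AOPP with IAA against L-AOPP, 44 and 93 became 27 and 39 with only the 2 groups, 5 and 18 without the trend and 22 and 48 with the covariate. With array weights 103 were higher, and 51 were lower with the 50% filter and 58 with only the 9 SAM arrays. Leaving out 1 array gave 9 to 60 higher and 18 to 153 lower. For L-AOPP with IAA against mock, 194 and 290 became 51 and 83 with only the 2 groups, 62 and 113 without the trend and 4 and 3 with the covariate, and 128 were higher with only the 9 SAM arrays. Without 1 array the ranges were 62 to 245 and 107 to 286. For SAM against whole plants, 6787 and 3973 became 3965 and 2291 with the covariate and ran from 6336 to 6707 and from 3622 to 3935 without 1 array. The 23 moved back became 14 with no filter, 14 with the 50% filter, 5 without the trend, 46 with array weights and 3 with the covariate, and ran from 4 to 38 without 1 array. The 50% filter and the smaller fits hold fewer probe sets or arrays, and for the other settings the cause was not tested.

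The replicate number as a block gave 120 higher and 167 lower, 30 and 70, 141 and 216, and 6715 and 3933 in the 4 comparisons. Deviations of same-numbered arrays correlated at -0.19 to 0.11 (18 pairs) and of others at -0.18 to 0.2, so the numbers show no pairing. Fold changes of dim genes such as ICL are limited by signal over background.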

Other observations

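All tests on the sets described here were chosen only after the results were seen. Of 68 probe sets of plastid genome genes, 66 were lower in mock SAM than in whole plants (median log2 -1.29, camera adjusted p 9.81e-15 over 20 sets, adjusted p 0.387 with an estimated correlation). With L-AOPP 1 of the 68 was higher than in mock, rpoC2 (0.92 ± 0.21 SE, n = 3, adjusted p 0.0342), chosen after its values were seen, and 52 of 68 lay above 0 (median 0.23, camera adjusted p 0.000245, adjusted p 0.517 with an estimated correlation). With L-AOPP and IAA against L-AOPP 0 passed and 59 of 68 lay above 0 (median 0.24, camera adjusted p 1.35e-06, adjusted p 0.798 with an estimated correlation). With L-AOPP and IAA 8 were higher than in mock and 62 of 68 lay above 0 (median 0.65, camera adjusted p 2.17e-15, adjusted p 0.693 with an estimated correlation of 0.496 between the genes). Their median was 0.44 with the GAPDH ratio as a covariate.

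Among 9 GSTU genes, for glutathione transferases, 7 were lower in mock SAM than in whole plants and 1 higher, GSTU20 (log2 1.59, chosen after its values were seen), with a median of -2.06 (camera adjusted p 0.00287, adjusted p 0.111 with an estimated correlation). Of 28 UGT genes, for glycosyltransferases, 12 were lower and 4 higher (camera adjusted p 0.0424, adjusted p 0.387 with an estimated correlation).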
